A study of Mus musculus with 2 samples.

How the data were processed

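Single-cell RNA sequencing had been run on wild-type mouse second heart field, the mesodermal progenitor population that adds cells to both poles of the heart tube, at embryonic day (E) 9.5 and E10.5. Per the labels, the tissue was dissociated with trypsin, loaded on the 10x Chromium controller and sequenced on a NextSeq, and the reads were aligned to mm10. Per the submitters' processing notes the tools were Cell Ranger 3.0 and Seurat with mm10. The annotation version was not given in the sources used here. The deposited values are raw UMI counts per gene and cell barcode, 1 matrix per stage, and the barcode suffix gives the dissected position per the labels. The labels call the cells Osr1+ without saying how they were chosen; in the values every cell had at least 1 Osr1 count.

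The matrices held 17492 genes and 533 cells at E9.5, and 17348 genes and 967 cells at E10.5. Symbols were matched to GENCODE vM21 on GRCm38 for 98.9% of genes at E9.5 and 99.0% at E10.5. The 16388 genes present in both matrices entered every analysis across stages; the genes present in 1 matrix only held 0.0255% of the E9.5 counts and 0.0140% of the E10.5 counts. No cell was removed in the main analysis. Scrublet (in scanpy 1.11.5, run per library with 20 principal components at most) marked 73 of the 1500 cells as doublets; these cells were kept, and an alternative left them out. In the smallest libraries the Scrublet share was 48.1% (E9.5 anterior), 44.4% (E10.5 anterior) and 35.5% (E10.5 outflow tract), against 3.28% or less in the others.

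For position, counts were summed over the cells of each library. The 6 libraries of the 3 positions dissected at both stages were fitted with edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, glmQLFit and glmQLFTest) on a model with stage and position. The stage samples were the replicates, which left 2 residual degrees of freedom. The filter kept 9825 genes, the common biological coefficient of variation was 0.217 and the median prior degrees of freedom were 7.2. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the fitted log2 fold divided by the square root of its quasi-likelihood F. The fit was tested on counts simulated from the mean of each stage and the trended dispersion. It recovered 17 of 65 genes changed by 1 on the log2 scale, 45 of 63 changed by 2 and 59 of 65 changed by 3. There were 3 false calls among 124. Changed genes that the filter removed were not counted. The simulation held no difference in cell types between libraries, so these rates need not hold for the real calls.

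No test was made between stages (1 sample each) or between the outflow tract and the anterior library (1 library each). There, counts scaled to library totals (CPM) are compared with exact conditional Poisson intervals (Clopper-Pearson on the split of counts, 95%), and the stage difference is the mean of the 3 position log2 folds with equal weight. All such intervals, and the exact Clopper-Pearson intervals of shares of cells, cover counting error only. Where no cell was counted, the limit given is 3 cells of the total, which is lower than the upper end of the 95% Clopper-Pearson interval. Against a library with 0 counts the fold is a bound computed with 3 counts in that library. Shares of cells with a UMI are given unthinned and after thinning each cell to 4500 UMIs (the 10th percentile over cells, rounded down), which left out 8 cells at E9.5 and 134 at E10.5.

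Cells of all libraries were clustered together in scanpy (counts per 10000 on a log scale, 2000 variable genes without Osr1, mitochondrial and haemoglobin genes, 20 principal components, 15 neighbours, Leiden in igraph 0.11.9 at resolution 0.6). A cluster was named after a cell type only when at least 3 of that type's listed markers were at least 1 higher on the log2 scale than in the other cells (at least 10% of cells with a UMI, 10 CPM added) and no other type had more markers among its 10 leading genes. Haemoglobin genes alone never named a cluster. Names end in "like" because they rest on markers alone.

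The gene lists (20), the markers of 16 cell types, the tests, the alternatives and the rule for named genes were fixed before the data were examined. For each list the median log2 fold of its measured members is given with its percentile among 10000 random lists matched on expression (20 bins). Fitted folds were used for the position fit, and 5 CPM were added for the medians within stages, between stages and for the outflow tract. Genes are not independent replicates, so percentiles describe these libraries only. The rule selected genes as follows, and some selected genes are not analysed here. For position it took the 12 called genes with the largest positive and the 12 with the largest negative fitted fold and 1 direction in both stages. For stage it took the 12 highest and 12 lowest mean folds among genes with at least 50 counts and at least a 2-fold difference of 1 direction at all 3 positions. For the outflow tract it took the 10 highest and 10 lowest folds with at least 30 counts and an interval without 1. Added to these were 22 key genes, up to 4 members per list with at least 50 counts, and the 5 largest called genes in each direction against the middle libraries. Unnamed predicted genes were passed over. Only 11 genes met the rule among the lower ones of the posterior against anterior comparison.

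Alternatives changed 1 choice at a time. They were DESeq2 1.42.0, size factors of the RLE type, library totals without scaling, other low-count filters, limma 3.58.1 on mean log values, no stage term, position as a trend, subsets of cells, genes left out, thinning, other clustering settings and each library or position left out. Near-identical copies of ribosomal protein genes were searched with BLAST 2.17.0 (at least 95% identity over at least 200 bases). The search covered the transcript sequences of the genes present in both matrices, and copies annotated outside these genes were not searched. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, scikit-learn 1.9.0 and matplotlib 3.10.9.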

Results

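The data were UMI counts of 1500 single cells taken from the second heart field of wild-type mice and described as positive for Osr1, a zinc finger gene of the posterior second heart field, kidney and limb mesoderm. The E9.5 sample held 533 cells from 3 dissected positions: 54 anterior, 61 middle and 418 posterior cells. The E10.5 sample held 967 cells from 4 positions: 31 outflow tract, 45 anterior, 331 middle and 560 posterior cells. There was 1 sample per stage, so each position was measured once per stage. Total counts were 16548509 at E9.5 and 5940977 at E10.5, with a median of 30208 UMIs per cell (964 to 105157) at E9.5 and 5371 (4092 to 45943) at E10.5. By library, totals ran from 1296187 (anterior) to 13647039 (posterior) at E9.5, and from 196584 (outflow tract) to 3448474 (posterior) at E10.5.

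Stage was measured together with sex and depth. Xist, the X inactivation transcript expressed in female cells, had a UMI in 1 of 533 cells at E9.5 (0.188%) and in 903 of 967 cells at E10.5 (93.4%). Osr1 (chromosome 12, 9570116 to 9581500, mm10) was at exactly 1 UMI in 25.8% of E9.5 posterior cells and 48.8% of E10.5 posterior cells, against 66.7% of E9.5 anterior, 95.6% of E10.5 anterior and 93.5% of outflow tract cells. Its level was 71.7, 122 and 168 CPM in the E9.5 anterior, middle and posterior libraries and 185, 251 and 317 CPM in the matching E10.5 libraries. Every cell had at least 1 Osr1 count, so fewer UMIs per cell force a higher lowest possible level. The higher Osr1 levels at E10.5 can come from this floor, so no stage difference is drawn from them. The fitted posterior minus anterior log2 fold of Osr1 was 0.92 ± 0.24 (SE, 6 libraries, adjusted p = 0.323), so it did not pass the test, and a choice of cells on Osr1, the rule of which is not known, can set this value.

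The comparison of posterior with anterior libraries asks which genes mark the ends of this field. Genes of posterior second heart field and foregut mesenchyme were higher in posterior cells at both stages. Barx1, a homeobox gene of stomach mesenchyme (chromosome 13, 48662998 to 48666507), rose by a log2 fold of 4.51 ± 0.43 (SE, 6 libraries, 2 stage samples; adjusted p = 0.00527). Hoxa5, which patterns lung mesenchyme, rose by 3.74 ± 0.37 (adjusted p = 0.00527), and Foxf1, a forkhead gene of foregut mesenchyme that responds to Hedgehog (chromosome 8, 121084386 to 121088144), by 3.74 ± 0.54 (adjusted p = 0.0347). Wnt2, a ligand of cardiopulmonary progenitors (chromosome 6, 17988940 to 18030585), had no count in either anterior library and was at least 67.4-fold higher in posterior cells at E9.5 and at least 3.61-fold higher at E10.5 (adjusted p = 0.0158). Tbx5, a T-box gene of the inflow tract and atria (chromosome 5, 119832668 to 119885219), was also at 0 in both anterior libraries and was at least 21.6-fold and 3.90-fold higher at E9.5 and E10.5 (adjusted p = 0.0347).

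In the other direction, several genes of the anterior and pharyngeal field fell towards posterior. Tbx1, the T-box gene of the pharyngeal second heart field (chromosome 16, 18580979 to 18590671), changed by −3.84 ± 0.37 (adjusted p = 0.00527), from 88.7 to 8.57 CPM at E9.5 and from 59.1 to 2.03 CPM at E10.5. Crabp1, a cytoplasmic retinoic acid binding protein (chromosome 9, 54764748 to 54773110), changed by −4.39 ± 0.40 (adjusted p = 0.00527), and Pax9, a pharyngeal pouch gene, by −7.22 ± 0.68 (adjusted p = 0.00527), with 2 anterior and 1 posterior counts at E10.5. Spry2, an FGF antagonist, changed by −3.03 ± 0.35, Irx1 by −2.85 ± 0.37, Ebf1 by −2.82 ± 0.43, Gng11 by −2.06 ± 0.33 and Hmgn3 by −1.60 ± 0.25. Crym and Gbx2 fell too, by −5.66 ± 0.83 and −5.60 ± 0.85, but like Pax9 each had 3 counts or fewer in both ends at 1 of the stages, so these folds rest on the other stage. At E9.5 the ends also differed in cell types, with 72.2% of anterior and 12.9% of posterior cells epithelium-like. At E10.5 the unnamed cluster 4 held 43 of 45 anterior and 23 of 560 posterior cells, and Crym and Crabp1 are among its leading genes. Part of the folds in either direction can therefore come from the cells sampled at both stages.

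Of 9825 genes tested with edgeR quasi-likelihood, 29 passed, 15 higher and 14 lower in posterior, and 594 had an unadjusted p under 0.05. Other genes higher in posterior were Rspo1, a Wnt agonist (4.92 ± 0.61, adjusted p = 0.0158), and Ttr, a thyroxine carrier (4.38 ± 0.69, adjusted p = 0.0455). Aldh1a2, the main retinoic acid synthesising enzyme of the embryo, was at least 60.9-fold higher at E9.5 and 23.3-fold higher (4.16 to 925) at E10.5, where the anterior library held 1 count (adjusted p = 0.00656). Gata4, a cardiac zinc finger gene, was 103-fold higher (18.5 to 4089) at E9.5, where the anterior library held 1 count, with no anterior count at E10.5 (adjusted p = 0.00656). Afp, a liver and yolk sac serum protein, was at least 2.44-fold higher at E9.5 and at least 15.6-fold higher at E10.5 (adjusted p = 0.0344). At E10.5 Afp had a UMI in 14.6% of posterior epithelium-like cells (6 of 41) as well as in 113 of 513 in unnamed clusters, and the cluster it leads also held Apoa2, Rbp4 and Ambp, so liver RNA from outside these cells stays possible as its source. Csrp3, a muscle LIM protein, was 27.3-fold higher (10.6 to 100) at E9.5 (adjusted p = 0.0455) with no anterior count at E10.5. Foxe1, at 61.7 CPM in the E9.5 anterior library and 0 in both posterior libraries, and Fgf8, a growth factor of the anterior field at 102.6 CPM there, passed on E9.5 alone, since both were at 0 in the E10.5 anterior library. DESeq2 called 45 genes, 18 higher and 27 lower, while limma on mean log values and a fit without the stage term called 0. Leaving out a library moved the count to 95 (without E9.5 anterior), 126 (E9.5 middle), 226 (E9.5 posterior), 254 (E10.5 anterior), 128 (E10.5 middle) or 332 (E10.5 posterior).

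**Figure D1:**
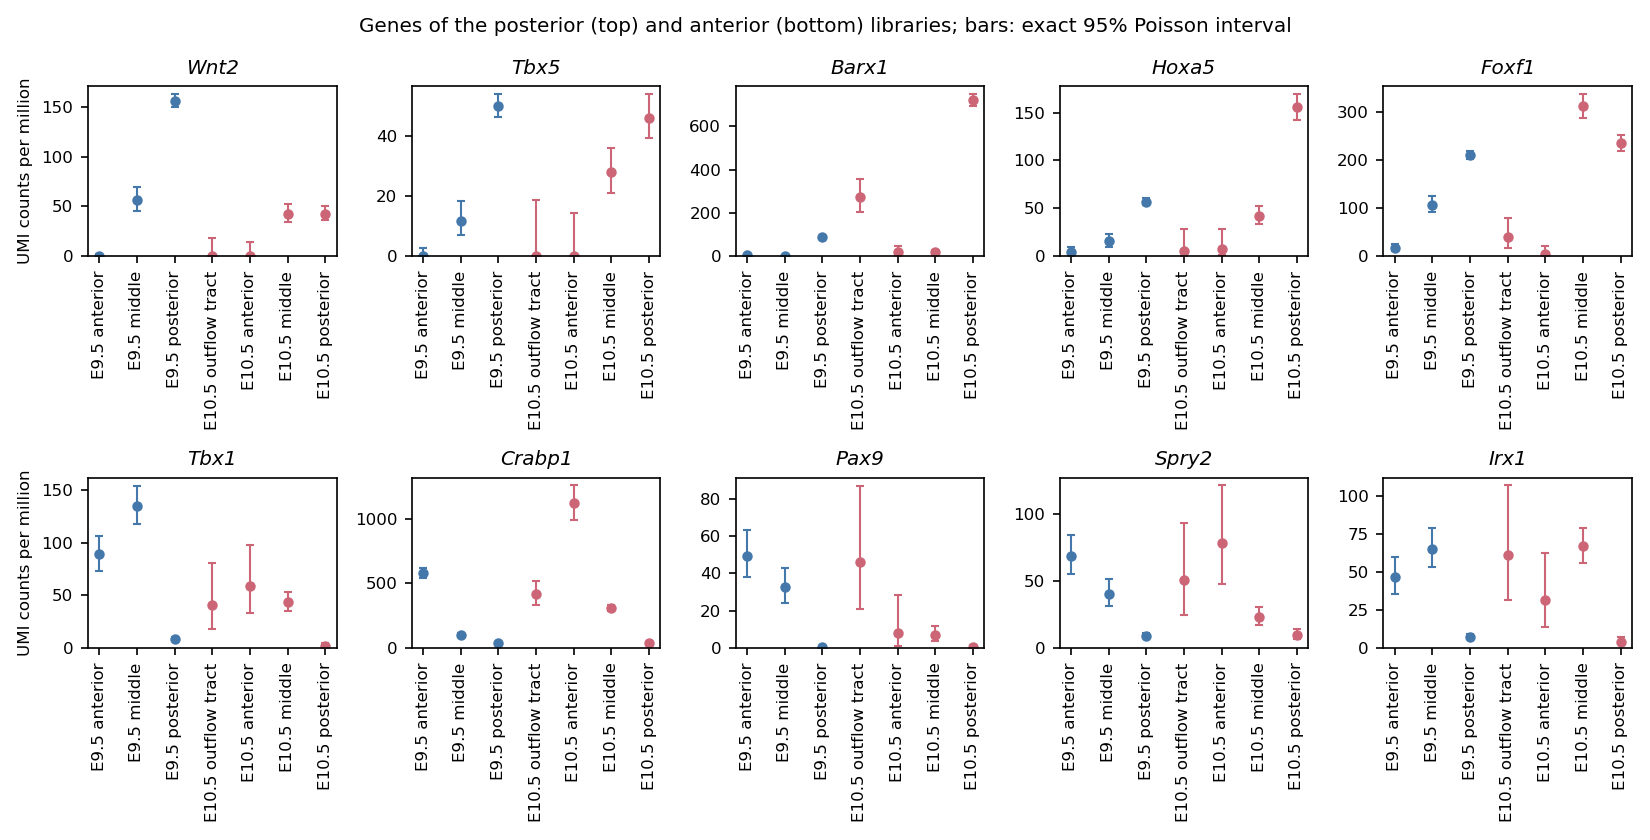
CPM of 10 genes in each of the 7 libraries (points), with exact 95% Poisson intervals that cover counting error only (bars). Wnt2 and Tbx5 were at 0 in both anterior libraries, while Tbx1, Crabp1, Pax9, Spry2 and Irx1 were lowest in the posterior library of each stage.

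The fixed gene lists of the 2 ends moved in opposite directions in the fit. Of 17 measured genes of the posterior second heart field and venous pole, 14 had a fold above 0 (median log2 1.95, percentile 100); 5 rose over all genes tested (Tbx5, Foxf1, Wnt2, Aldh1a2 and Gata4) and 11 adjusted over the list alone, among them Gata6, Hoxb1 and Nr2f2. Of 14 genes of the anterior and pharyngeal second heart field, 11 had a fold below 0 (median −1.28, percentile 0); 3 fell over all genes, Tbx1 and Fgf8 among them, and 1 rose (Dlk1) and 7 fell adjusted over the list alone, Eya1, Irx3 and Irx5 included. Within stages this list was 3 higher and 11 lower at E9.5 (median −1.08) and 6 higher and 8 lower at E10.5 (median −0.55). Hox genes of paralogue groups 1 to 6 had a median of 1.80 over 12 genes (1.56 with Hoxc5, absent from both anterior libraries, at its bound); Hoxa5 rose over all genes and 8 rose adjusted over the list alone. Lung and foregut mesenchyme genes had a median of 4.51 over 7 genes (3.20 with Tbx5, Wnt2 and Nkx6-1 at their bounds); 4 rose over all genes, and 5 rose and 1 fell (Nkx2-3) adjusted over the list alone. Within E10.5 all 7 had a fold above 0, Nkx2-3 included, so its fall rests on E9.5.

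Signalling lists moved in part. FGF pathway genes had a median of −1.53 over 11 genes (percentile 0), with Fgf8 and Spry2 lower over all genes and 1 higher (Fgfr2) and 4 lower adjusted over the list alone, the others being the FGF targets Etv4 and Dusp6. Within stages this median was −1.77 at E9.5 and 0.53 at E10.5. Hedgehog pathway genes and targets had a median of 0.58 over 13 genes; Foxf1 rose over all genes, and 4 rose adjusted over the list alone (Gli1, Foxf1, Foxl1 and Osr1, the last of which a choice of cells on Osr1 can set). The retinoic acid list had a median of −0.36 over 11 genes, with Aldh1a2 higher and Crabp1 lower over all genes, and Crabp2 lower too adjusted over the list alone (1 higher, 2 lower). Wnt pathway genes (median 0.09 over 18 genes; Wnt2 higher over all genes, 2 higher and 1 lower adjusted over the list alone) and BMP pathway genes (−0.03 over 18 genes; 0 called over all genes or adjusted over the list alone) went both ways. Outflow tract and conotruncal markers had a median of −0.28 over 10 genes (0 over all genes; Plxna2 higher and Wnt5a lower adjusted over the list alone), with −0.42 within E9.5 and 0.92 within E10.5. BMP genes also changed sign, from −0.37 to 0.58.

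Lists of contractile, matrix, cell cycle and metabolic genes were also measured. Cardiac sarcomere genes had a median of 2.10 over 14 genes, with Myl4, an atrial light chain (2.32 ± 0.35, adjusted p = 0.0383), and Csrp3 higher over all genes and 10 higher adjusted over the list alone. Cardiomyocyte-like cells made up 7.66% of E9.5 posterior cells (32 of 418) and 3.70% of anterior cells (2 of 54). The posterior share depended on the clustering: it was 35.9% at resolution 0.3, 17.2% with 30 principal components, 14.4% without cell cycle genes and 17.0% with each stage clustered alone. Without cells of other named types the sarcomere median was −0.95. Mitochondrially encoded genes had a median of 0.55, with 13 of 13 above 0 and 0 past the test over all genes or adjusted over the list alone; within E9.5 it was −0.08 and within E10.5 it was 1.87. Median log2 folds were 0.32 for S phase (20 genes), 0.08 for G2 and M phase (20), −0.11 for glycolysis and hypoxia (15), −0.37 for haemoglobins (7) and −0.30 for smooth muscle (8), each with 0 calls over all genes or adjusted over the list alone. Extracellular matrix (0.15 over 23 genes; Col5a2 higher), developmental timing (−0.03 over 18; Dlk1, Plagl1 and Nfib higher) and immediate early and heat shock genes (0.05 over 12; Ier2 lower) had calls only adjusted over the list alone. Within E9.5 and E10.5 the medians had opposite signs for smooth muscle (0.08 and −1.06), developmental timing (−0.17 and 0.66), haemoglobins (−0.57 and 0.54) and G2 and M phase (0.13 and −0.12). The median of all 9825 genes was 0.02 in the fit and 0.21 within E10.5.

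Markers of other cell types differed between the ends as well. Foregut endoderm or epithelium markers had a median log2 fold of −0.93 over 9 genes in the fit, −2.07 within E9.5 and 1.45 within E10.5. Cardiomyocyte markers had a median of 1.89 (7 genes), epicardial or mesothelial markers 0.60 (7), endothelial markers 0.99 (4), erythroid markers −0.12 (6), neural crest markers −0.83 (4), cushion mesenchyme markers −0.56 (8), neural markers −0.63 (3), somite markers −2.06 (5), nephric markers −2.93 (3), branchiomeric muscle markers 1.17 (4), lung or foregut mesenchyme markers 4.51 (5), smooth muscle markers −0.51 (4) and second heart field markers 0.31 (9). Of the hepatoblast markers only Afp and Ttr were measured, and both rose; no leukocyte marker was measured. Opposite signs within E9.5 and E10.5 were found for second heart field (−0.22 and 2.79), smooth muscle (0.79 and −2.49), epicardial (−0.24 and 1.54), erythroid (−0.71 and 0.73), cushion mesenchyme (0.34 and −0.90), neural (0.11 and −2.04), nephric (−2.43 and 0.16) and neural crest markers (−0.09 and 0.04).

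The middle libraries shared genes with each end. Tbx1, Irx1 and Pax9 were near their anterior levels in middle cells and fell from middle to posterior, by −4.07 ± 0.34, −3.58 ± 0.33 and −6.61 ± 0.65 (SE, 6 libraries; adjusted p = 0.00286, 0.00288 and 0.00390). Irx2 (−2.81 ± 0.36, adjusted p = 0.0188) and Ripply3, a repressor that binds T-box proteins (−2.89 ± 0.44, adjusted p = 0.0480), were the other genes lower in posterior. Ripply3 is among the leading genes of the epithelium-like cluster 7, which held 34.4% of E9.5 middle and 12.9% of E9.5 posterior cells. Wnt2, Tbx5, Foxf1 and Aldh1a2 were already present in middle cells: Foxf1 was at 108 and 313 CPM in the E9.5 and E10.5 middle libraries against 17.0 and 3.94 CPM in anterior, and Wnt2 was at 56.8 and 42.6 CPM against 0. Barx1 rose from middle to posterior by 5.21 ± 0.40 (adjusted p = 0.00286), Gata4 by 3.97 ± 0.41 (adjusted p = 0.00473) and Hoxa5 by 1.78 ± 0.25.

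Posterior against middle gave 19 genes, 14 higher and 5 lower in posterior. Contractile genes, which lead the cardiomyocyte-like cluster 10 (32 of 418 E9.5 posterior and 0 of 61 E9.5 middle cells), were among the higher ones: Myl4 (3.88 ± 0.35), Tnnt2 (3.11 ± 0.39) and Myl7 (2.71 ± 0.39), with Myh6, at 0 in both middle libraries, at least 32.4-fold higher at E9.5 and at least 7.50-fold higher at E10.5 (adjusted p = 0.0164). Tnnc1 was at least 80.6-fold higher at E9.5 and 7.69-fold higher (2.83 to 29.3) at E10.5 (adjusted p = 0.0480), and Csrp3 at least 45.0-fold and 20.7-fold (3.48 to 841). Afp, also at 0 in both middle libraries, was at least 3.01-fold higher at E9.5 and at least 125-fold higher at E10.5. Middle against anterior gave 0 genes by edgeR quasi-likelihood, with 345 at an unadjusted p under 0.05 and 4 called by DESeq2 (Wnt2, Foxf1 and Aldh1a2 higher, Crabp1 lower; named after their values were seen). DESeq2 called 33 genes for posterior against middle, 17 higher and 16 lower; limma on mean log values and the fit without the stage term called 0, and leaving out a library gave 37 to 231. Without cells of other named types 43 genes were called, with 8 of the 19 among them.

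E10.5 and E9.5 were compared at the 3 shared positions to ask what changes over a day of development, with 1 sample per stage and no test. Lin28a, an RNA binding protein that blocks let-7 maturation (chromosome 4, 134003330 to 134018841), was lower at E10.5 at every position, with a mean log2 fold of −4.32 (anterior −5.36, −10.67 to −2.87; middle −4.36, −5.30 to −3.56; posterior −3.22, −3.76 to −2.73). Cardiac genes were lower too: Myl7 by a mean of −4.05, Nkx2-5, a homeobox gene of cardiac progenitors, by −4.02, Tnnt2 by −3.87 and Myl4 by −3.82. At E9.5 Nkx2-5 was highest in anterior, with 130 CPM against 38.1 in middle and 80.2 in posterior. Of those anterior cells 39 of 54 were epithelium-like and 2 of 54 cardiomyocyte-like, so its fold can come in part from the cells sampled. The sarcomere list had a median of −1.34 (12 of 14 genes below 0). Cardiomyocyte-like cells were 32 of 418 in E9.5 posterior and 1 of 560 in E10.5 posterior cells. With each stage clustered alone they were 17.0% (71 of 418) and 17.9% (100 of 560), so the share of cells given this name depended on the clustering. At posterior all 14 sarcomere genes were lower at E10.5 (median −2.34, highest −0.93). These values argue against an equal share of cells with equal levels of sarcomere genes at both stages. A smaller share and lower levels per cell were not told apart. Haemoglobin transcripts were higher at E10.5 in every library, with a list median of 3.84, mean folds of 5.83 for Hba-a1, 5.57 for Hba-a2, 5.43 for Hba-x and 5.07 for Hbb-y, and haemoglobin shares of 0.109% to 0.556% of counts against 0.00337% to 0.0152% at the same positions. Haemoglobin UMIs were found in cells of named and unnamed clusters: after thinning, Hbb-y was in 97.7% of E10.5 posterior cells of unnamed clusters and in 100% of epithelium-like cells (37 of 37), with median depths of 5580 and 6559 UMIs.

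Other named genes lower at E10.5 were the glucose transporter Slc2a3 (−3.77), the carbonic anhydrase Car4 (−3.76), the imprinted gene Phlda2 (−3.74), the tight junction gene Cldn6 (−3.31) and Cyr61 (−3.15). Cldn6 and Car4 lead the E9.5 epithelium-like cluster 7, and epithelium-like cells went from 72.2% to 0 of 45 in anterior and from 34.4% to 4.23% in middle cells, so their folds can come from the cells sampled. Those higher were Xist (9.69 as a mean of bounds at 2 positions and a posterior value of 13.46), the mitochondrial import subunit Pam16 (6.17), Crym (5.02) and Eid2 (4.76). The rest were ribosomal protein genes and copies of them. Rps12 (6.69), Rpl10 (6.14), Rpl29 (5.23) and Rpl9 (4.75) were higher at E10.5, while the processed copies Rpl13a-ps1 (−4.13) and Rpl7a-ps5 (−3.40) were lower. Of 77 ribosomal protein genes, 8 moved by at least 2 on the log2 scale and 7 of these were higher; the median of the other 69 was −0.15 (quartiles −0.64 and 0.31), and the summed share of counts was 24.3% at E9.5 and 24.0% at E10.5. The means of Crym, Nkx2-5, Tnnt2, Car4, Cldn6 and Rpl13a-ps1 include a bound at 1 position with 0 counts at 1 stage. Pam16 was at 1.25 to 1.54 CPM at the 3 E9.5 positions and at 89.3 to 114 CPM at the same E10.5 positions. Eid2 was at 3.09 to 3.75 and at 75.4 to 122 CPM. Copies were searched for ribosomal protein genes only, so a different assignment of reads was not checked for Pam16 and Eid2.

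**Figure D2:**
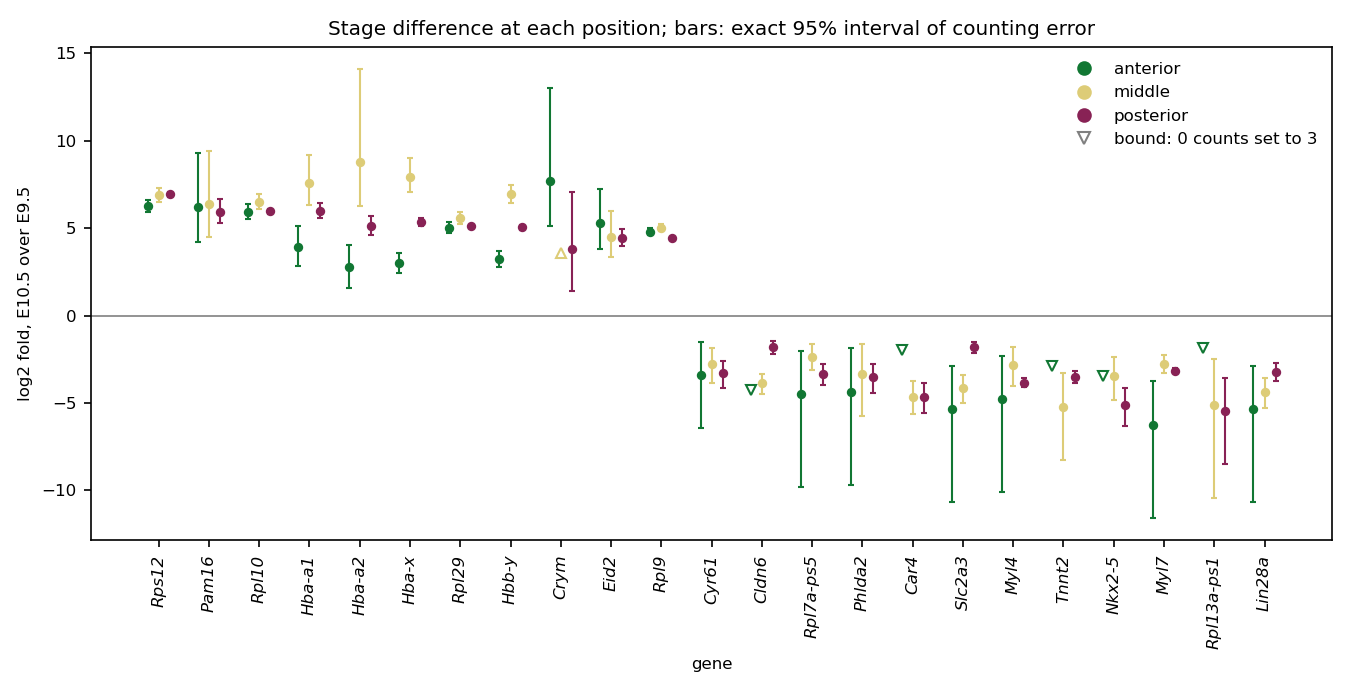
Log2 fold of E10.5 over E9.5 at each of the 3 shared positions (colours) for the named genes other than Xist, with exact 95% intervals of counting error as bars and open triangles for bounds against 0 counts. Lin28a lies below 0 at every position, with a mean of −4.32.

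**Figure D3:**
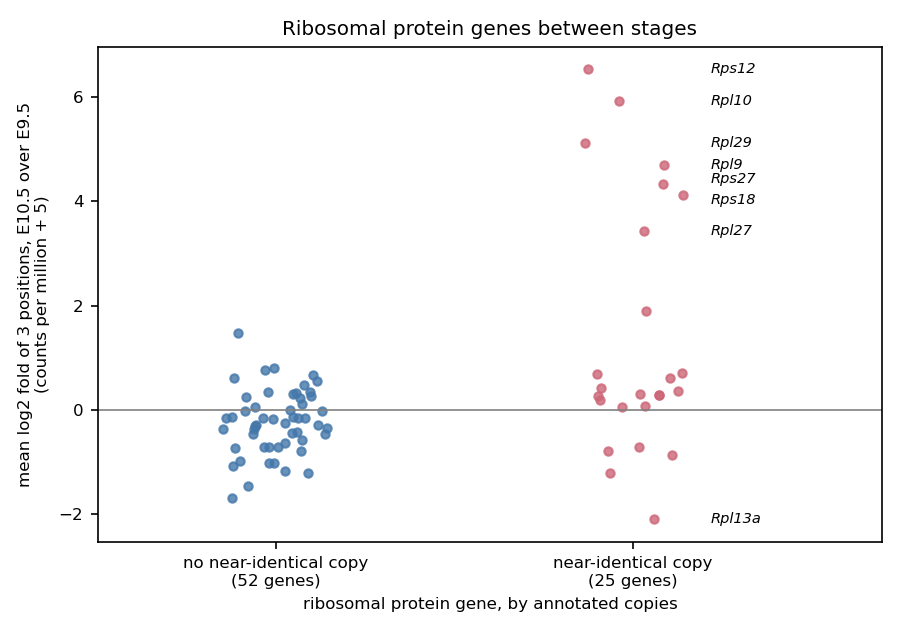
Mean log2 fold of the 3 positions (E10.5 over E9.5, 5 CPM added) for 77 ribosomal protein genes (points), split by whether an annotated near-identical copy exists among the genes present in both matrices (25 genes with, 52 without). The 8 named genes that moved by at least 2 all lie among the 25 with a copy.

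Several fixed lists differed between stages. G2 and M phase genes had a median log2 fold of 0.69 (18 of 20 above 0; Top2a 1.13, Hmmr 1.31), and S phase genes −0.41 (17 of 20 below 0; Ung −1.71, Cdt1 −1.18). Extracellular matrix genes had a median of 0.50 over 23 genes (Col3a1 2.87, Lum 2.87), glycolysis and hypoxia genes −0.69 over 15 (Pdk1 −2.10, Slc2a1 −1.34), Hox genes 0.63 over 12 (Hoxa4 4.09, Hoxb1 −2.68) and anterior second heart field genes −0.99 over 14 (Fgf8 −2.42, Foxc1 1.40). In the developmental timing list Nfia (4.02), Hmga1 (3.59) and Nfib (2.98) were higher and Lin28a lower, and the median was −0.19 over 18 genes. The gene means of Nfia, Hmga1, Hoxa4, Lum and Fgf8 include a bound at 1 position. Medians were −0.03 for posterior second heart field genes, −0.66 for FGF, −0.35 for BMP, −0.34 for Hedgehog, 0.04 for Wnt and 0.08 for retinoic acid genes, −0.17 for conotruncal markers, −0.18 for smooth muscle, −0.38 for immediate early and heat shock, −0.35 for mitochondrially encoded and 0.12 for lung and foregut mesenchyme genes. Epithelium markers had a median of −1.28 and cardiomyocyte markers of −3.10. At posterior alone the sign was the other for FGF (0.27), mitochondrially encoded (0.47), conotruncal (0.23), developmental timing (0.21) and retinoic acid genes (−0.45) and for epithelium markers (0.09). Smooth muscle genes were at 0.50 in anterior, 0.94 in middle and −0.31 in posterior, BMP genes at −0.98, 0.14 and −0.19, Hedgehog genes at −0.82, 0.11 and −0.05, and Wnt genes at −0.38, 0.53 and 0.19. The median of all 9825 genes was −0.09. Sex, depth and stage differ together here and cannot be separated with 1 sample per stage.

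The outflow tract was dissected at E10.5 only and was compared with the anterior library of that sample to ask what sets apart the arterial pole, with 1 library each and no test. Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), was at 10.2 CPM in outflow tract and 528 CPM in anterior cells, a log2 fold of −5.70 (−8.76 to −3.82), and the smooth muscle list had a median of −1.23 over 7 genes. Barx1 was at 275 CPM against 19.7 CPM, a log2 fold of 3.80 (2.49 to 5.48). Other named genes lower in outflow tract were Itm2a (−3.13), Actc1 (at most −3.05, 0 counts), Bdnf (−2.44), Mlf1 (−2.14), Tsc22d3 (−2.06), Spag9 (−1.95), Taf12 (−1.75), Nnat (−1.74) and Atic (−1.69). Those higher were Ddx3x (1.78), Zrsr2 (1.77), Igfbp5 (1.74), Gtf2i (1.72), Pkdcc (1.71), Ktn1 (1.69), Pgrmc2 (1.66) and Mpped2 (1.66). Tbx5 and Wnt2 had no count in either library, and Isl1, a LIM homeobox gene of the second heart field, was at 56.0 and 11.8 CPM (log2 fold 2.24, 0.32 to 4.73). In outflow tract, Isl1 had a UMI in 3 of 5 epithelium-like cells and in 3 of 26 cells of unnamed clusters (11.5%, 2.45 to 30.15). In anterior, where no cell was epithelium-like, it was in 1 of 45 cells (2.22%, 0.056 to 11.8), so in unnamed clusters the intervals overlapped.

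Median log2 folds of outflow tract over anterior cells were 0.75 for mitochondrially encoded genes (11 of 12 above 0), 0.38 for G2 and M phase genes (16 of 20) and 0.52 for BMP genes (9 of 11). The anterior library had the lowest mitochondrial share of the E10.5 libraries, 0.912% of counts against 1.60% in outflow tract, 1.34% in middle and 2.83% in posterior cells. Epithelium markers had a median of 2.61 over 4 measured genes, with 5 of 31 outflow tract cells and 0 of 45 anterior cells epithelium-like (0 of 45 allows up to 6.67%). Other medians were 0.39 for anterior and 0.27 for posterior second heart field genes, 0.08 for conotruncal markers, 0.49 for Hedgehog, −0.27 for retinoic acid, −0.04 for Hox, 0.08 for Wnt and −0.26 for FGF genes. The remaining lists had medians of −0.04 for sarcomere (3 genes), 0.28 for extracellular matrix, −0.04 for S phase, −0.07 for developmental timing, 0.35 for immediate early and heat shock, −0.13 for glycolysis and hypoxia and −0.28 for haemoglobins; of the lung and foregut mesenchyme list 2 genes were measured and both were higher. With 31 and 45 cells and 196584 and 253908 counts, smaller differences were not detectable at this depth.

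Shares of cells with a UMI followed the position levels. Tbx5 had a UMI in 49.5% of E9.5 posterior cells and 21.2% of E10.5 posterior cells; after thinning to 4500 UMIs the shares were 16.6% (13.1 to 20.5, 68 of 410) and 17.4% (14.1 to 21.1, 82 of 471). Thinned shares in the middle libraries were 8.20% (2.72 to 18.1) at E9.5 and 32 of 291 cells at E10.5, and 0 of 54 and 0 of 40 anterior cells had a Tbx5 UMI, which allows up to 5.56% and 7.50%. Only 12 of the 54 E9.5 anterior cells were in unnamed clusters, and 0 of 12 has an exact upper end of 26.5%. In E9.5 posterior cells of unnamed clusters the thinned share was 18.8% (14.0 to 24.3), so a lower thinned share in such anterior cells is not shown at E9.5. Unthinned, 0 of 12 stood against 56.2% of 242 cells, with median depths of 19900 and 30970 UMIs. In epithelium-like cells, which should lack Tbx5, the thinned share was 2.04% (1 of 49) in E9.5 posterior and 2.70% (1 of 37) in E10.5 posterior cells, with median depths of 31260 and 6559 UMIs against 31030 and 5580 in unnamed clusters. Thinned Wnt2 shares were 34.1% and 13.2% in posterior cells of the 2 stages (4.08% and 0% in their epithelium-like cells) and Foxf1 shares 46.6% and 60.3% (6.12% and 8.11%). In unnamed clusters alone the Foxf1 shares were 72.5% and 65.4% and the Wnt2 shares 32.1% and 14.2%, so the order of the stages for Foxf1 depended on the cell types in each library. Thinned Tbx1 shares were 18.5% and 27.5% in anterior, 39.3% and 14.4% in middle and 3.90% and 0.637% in posterior cells at E9.5 and E10.5.

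Clustering gave 11 clusters that divided almost fully by stage, so a cluster can reflect its sample as well as a cell type. Unnamed clusters held most E10.5 cells, and 5 clusters were named: 7 and 9 foregut endoderm or epithelium-like, 8 epicardial or mesothelial-like, 10 cardiomyocyte-like and 11 endothelial or endocardial-like. Epithelium-like cells made up 72.2% of E9.5 anterior (39 of 54, exact interval 58.4 to 83.5), 34.4% of middle (22.7 to 47.7) and 12.9% of posterior cells (9.86 to 16.5), all in cluster 7. At E10.5 they were in cluster 9, with 0 of 45 anterior, 4.23% of middle (2.33 to 6.99) and 7.32% of posterior cells (5.30 to 9.80). Epicardial-like cells were 19.7% of E9.5 middle and 19.9% of E9.5 posterior cells, against 1 of 54 anterior cells and none at E10.5. This class depended on the clustering: no E9.5 cell was named so at resolution 0.3 or 1.0, and 9 of 54 anterior cells were without cell cycle genes. In the E9.5 anterior library the epithelium-like share was 1.85% at resolution 1.0 and 27 of 54 cells when each stage was clustered alone. In the latter setting 13 of 54 anterior, 23 of 61 middle and 44 of 418 posterior cells at E9.5 were endothelial-like. The main clustering gave 0, 0 and 7. Only 3 of 45 E10.5 anterior and 5 of 31 outflow tract cells stayed unnamed, against 45 and 26 in the main clustering. Most cells of these E10.5 libraries then carried the name of a further type, which was not examined. A choice of cells on Osr1 and the depth gap between stages can set these shares.

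**Figure D4:**
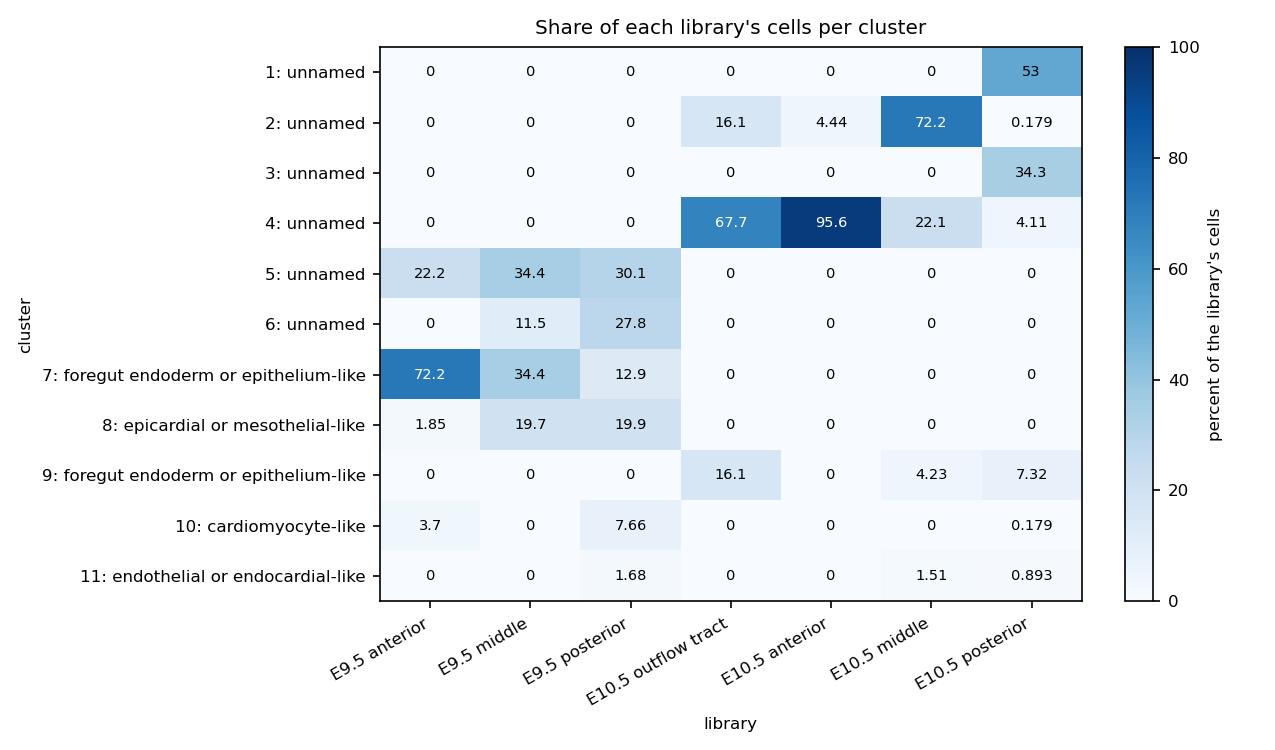
Percent of each library's cells (columns) in each of the 11 clusters (rows), from 0 (white) to 100 (dark). E9.5 and E10.5 libraries share few clusters, and epithelium-like cluster 7 holds 72.2% of the E9.5 anterior cells.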

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

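All tests in this part were chosen only after the result was seen. Among 97 named genes, 5 had a posterior minus anterior fold of opposite sign in the 2 stages, each with intervals that exclude 0; these differences between stages were not tested, since there was 1 sample per stage. Isl1 had log2 folds of −1.03 (−1.24 to −0.82) at E9.5 and 3.39 (1.83 to 5.67) at E10.5. Rgs5, a regulator of G protein signalling, was −3.06 (−3.49 to −2.63) at E9.5 and at least 0.76 at E10.5, where the anterior library held no count. Acta2 was 0.73 (0.57 to 0.88) at E9.5 and −3.85 (−4.21 to −3.49) at E10.5. It is among the leading genes of cardiomyocyte-like cluster 10 (4907 CPM), which held 32 of 418 E9.5 posterior and 2 of 54 E9.5 anterior cells. Its sign at E9.5 can come from these cells, which was not tested. The mitochondrial gene mt-Atp6 was −0.09 (−0.12 to −0.05) and 1.95 (1.81 to 2.10), and the haemoglobin gene Hba-x −1.41 (−1.90 to −0.90) and 0.95 (0.60 to 1.32). A signal outside the shared genes also appeared: Y-linked genes, listed in the E9.5 matrix only, had a UMI in 477 of 533 E9.5 cells (89.5%), with Eif2s3y in 371 cells and Ddx3y in 291.

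Without epithelium-like and other named cells the E9.5 fold of Isl1 was −0.89 (−1.25 to −0.51). It kept its sign, with 12 anterior and 242 posterior cells and an interval of counting error only. After thinning, Isl1 had a UMI in 7 of these 12 anterior cells (27.7% to 84.8%). In such posterior cells the share was 34.6% (28.6 to 41.0, 240 cells). The intervals overlap, so 12 cells cannot decide whether the named cells caused the sign at E9.5. The E10.5 anterior library was nearly all cluster 4 (43 of 45 cells). Cluster 4 cells of the other E10.5 libraries were also low in Isl1, with 8.49 CPM (6 counts, 117 cells) against 128 CPM in posterior cells outside cluster 4 (537 cells), a log2 fold of −3.92 (−5.37 to −2.78); against the E10.5 anterior library their fold was −0.48 (−2.70 to 2.15). A candidate explanation is that a different cell population was sampled as anterior at E10.5, which rests on 3 Isl1 counts in that library. Stage itself, as a biological difference, and the border of the dissection stay open and untested.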

How the results depend on the processing

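All alternatives in this part were planned before the data were examined, and none was added later. Position was compared within stage samples through the stage term, without which no gene was called. Between stages, no paired analysis was possible because there was 1 sample per stage and the labels name no embryo or litter that the stages share. For posterior against anterior (29 genes) the count was 45 with DESeq2, 260 with no low-count filter, 75 without doublets, 78 with cells of at least 2 Osr1 UMIs, 19 with equal cell numbers, 58 without other cell types, and 0 with limma on mean log values or with no stage term. For middle against anterior (0 genes) it was 4 with DESeq2, 64 with no filter, 2 with a filter of at least 10 counts, 4 without doublets, 34 with at least 2 Osr1 UMIs, 3 with equal cell numbers and 7 without other cell types. For posterior against middle (19 genes) it was 33, 178, 40, 49, 70, 8 and 43 under the same settings, and 0 with limma or with no stage term. Leaving out each library in turn gave 95 to 332, 14 to 123 and 37 to 231 genes; in such fits the lone library of a position is assumed to vary like the others. The higher counts with no filter come with more genes tested (16193 against 9825). The setting of at least 2 Osr1 UMIs left 2 E10.5 anterior and 18 E9.5 anterior cells. Its counts of genes therefore rest on very few anterior cells. The cause of the other changes in count was not tested. Size factors of the RLE type, library totals alone, the filter on cell quality and leaving out haemoglobin, mitochondrial and ribosomal genes kept all 3 counts within 1.5 times, as did the linear trend (21), run for posterior against anterior only. DESeq2 shared 27 of the 29 calls and 15 of the 19, in the same direction, and the fit without other cell types 21 and 8.

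Of 939 values of 97 posterior minus anterior folds, 780 stayed on their side of the threshold, 27 lost a call, 130 gained one and 2 reversed. A reversal was counted only where the main or the alternative fit called the gene. Changes of sign without a call are among the 780, as with Isl1 under DESeq2 (0.48, from −0.07). The reversed ones were both without the E9.5 anterior library: Isl1 from −0.07 to 3.20 (adjusted p = 0.00440; range over libraries left out −1.002 to 3.20) and Fgf8 from −5.71 to 4.01 (range −6.06 to 4.01), where the remaining anterior library held 0 Fgf8 counts. List medians were counted as reversed only for lists at an extreme percentile of the random lists. Without other cell types 3 did so: outflow tract and conotruncal markers (0.00291, from −0.28), cardiac sarcomere (−0.95, from 2.10) and haemoglobins (0.43, from −0.37). The cause was not tested except that the sarcomere alternative removes the cardiomyocyte-like cells. Of the other list medians 112 kept their value within the spread of members and 3 moved. Stage folds kept their value within counting error in 743 of 895 cases and outflow tract folds in 166 of 170. No sign reversed among stage folds with intervals on 1 side of 0 at all 3 positions, or among outflow tract folds with an interval without 0. Sign changes of other folds were not counted as reversals. The Tbx5 share moved from 49.5% to 16.6% when thinned and to 33.3% with at least 2 UMIs (E9.5 posterior), and from 21.2% to 17.4% and 5.54% (E10.5 posterior), which depth sets by construction. The epithelium-like share of E9.5 anterior cells moved from 72.2% to 1.85% at resolution 1.0 and 27 of 54 cells (50%) with each stage clustered alone. Depth limits the anterior and outflow tract libraries at E10.5 most, where 3 counts are 11.8 and 15.3 CPM.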

Other observations

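All tests in this part were chosen only after the result was seen. Within unnamed clusters of the posterior libraries, thinned to 4500 UMIs, Barx1 was found less often in cells with Wnt2 than in cells without. At E10.5 Barx1 had a UMI in 14.8% (6.98 to 26.2) of 61 cells with Wnt2 and in 59.4% (54.2 to 64.5) of 367 cells without. At E9.5 the shares were 15.6% (8.32 to 25.6) of 77 cells and 35.0% (27.7 to 42.8) of 163 cells. Tbx5 and Wnt2 went together at E9.5: Wnt2 was in 51.1% (35.8 to 66.3) of 45 cells with Tbx5 and in 27.7% (21.5 to 34.5) of 195 cells without, and Barx1 in 6.67% (1.40 to 18.3) and 33.8% (27.2 to 41.0). In E10.5 posterior cells the intervals of the Wnt2 shares overlapped (12.7% to 31.5% of 81 cells with Tbx5, 9.37% to 16.6% of 347 without). In E10.5 middle cells, Isl1 was in 46.9% (29.1 to 65.3) of 32 cells with Tbx5 and in 20.4% (15.5 to 26.1) of 240 without, but in E10.5 posterior cells the order was the opposite, 22.2% (13.7 to 32.8) of 81 and 39.8% (34.6 to 45.1) of 347, and in E9.5 posterior cells the shares were 28.9% (16.4 to 44.3) and 35.9% (29.2 to 43.1). These genes were chosen after their values were seen. Each share pools the unnamed clusters of its library. Barx1 is among the leading genes of cluster 3 (unthinned, 86.5% of its cells), which held 192 of 560 E10.5 posterior cells. It is also among those of cluster 6 (74.8%), which held 116 of 418 E9.5 posterior cells. The orders can therefore come from the split of cells between clusters, which was not tested.

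A few ribosomal protein genes differed strongly between stages. All 8 that moved by at least 2 on the log2 scale have an annotated near-identical copy among the genes present in both matrices. This is a share of 100% (exact interval 63.1 to 100), against 24.6% (15.1 to 36.5) of the other 69. Copies outside these genes were not searched. The 7 that were higher at E10.5 all had copies lower at E10.5, but Rpl13a and its copy were both lower (−2.09 and −2.56). With the counts of copies added the median of the 8 was 3.08 against 4.52, so a shift of reads between the copies searched cannot be the whole cause. A change of ribosomal protein genes as a group is argued against by the median of all 77, which was −0.02. The other 69 had a median of −0.15 (quartiles −0.64 and 0.31), but they were set apart by their smaller change. A candidate explanation is that reads shared between copies were assigned or dropped differently in the 2 stage samples; a difference of read length or annotation between them stays open, since the sources used here do not give either per sample.

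Osr1, for which the labels call the cells positive, was found beyond the first UMI in part of the epithelium-like cells. In 54 such cells of the E9.5 posterior library Osr1 beyond the first UMI of each cell was at 56.2% (47.6 to 65.9) of its level in cluster 5, with 163 of all 234 Osr1 counts in 20 cells, while the sum of 6 mesenchyme markers was at 6.72% (5.02 to 8.82), which argues against doublets with mesenchymal cells as the whole source. Osr1 counts beyond the first UMI per cell stood to Foxf1 counts as 10.0 (6.15 to 17.3), against 0.648 in the whole library, which argues against free RNA of that library. In the E10.5 epithelium-like cluster 9 the mean was 1.53 Osr1 UMIs with 70% of cells at exactly 1, and in the E9.5 anterior library it was 1.72 with 66.7% at exactly 1, so the pattern was tested in E9.5 posterior cells only. Expression of Osr1 in these cells may be a biological feature of the epithelium, which was not tested, and the unknown rule that chose the cells stays open.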
